A study of Bacillus subtilis with 12 samples.

How the data were processed

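The series measured messenger RNA levels of the Bacillus subtilis laboratory wild type on 2-colour DNA microarrays. Cultures grew in batch fermentors at 37 °C in minimal medium of pH 6.4. At an optical density of 0.2 they received 25 mM potassium acetate, a weak organic acid, or 0.85 µM CCCP, a protonophore that uncouples respiration from ATP synthesis. On each array a treated culture (Cy5, red) was set against an untreated control culture sampled at the same time (Cy3, green), before addition (0 min) and then every 10 min up to 50 min. There were 12 samples, each with 2 arrays from independent experiments, so 24 arrays. The labels name no dye swap.

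The deposited series table holds log2 ratios of Cy5 over Cy3 for 4100 gene symbols in 12 columns. Per the labels each column is the average of both arrays, and from the values it was normalised within arrays by an intensity-dependent curve. The authors' filters and their handling of missing values are not given in the sources used here; 686 values of the table are exactly 0. The scanner files give, per the file headers, the spot density and local background of each channel as intensity, not normalised, and a further intensity column that equals their difference with negative values set to 0. Per the file headers they also give a signal-to-noise score for each spot and channel. The share of a spot's pixels at the scanner's ceiling is a percent per the file headers. Each file holds 9216 spots, which are 4608 features printed at 2 positions; the software that made the files is not given in the sources used here.

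The scanner files carry spot positions and no gene names, and no array design was available. Genes were therefore linked to features by their values: for each gene of the deposited table, the feature was sought whose normalised log2 ratios came nearest to the gene's 12 values. A link needed at least 4 values, a mean difference of at most 0.1 on the log2 scale (single differences capped at 0.5), a second nearest feature at least 2 times as far, and a feature whose own nearest gene was that gene. Values of exactly 0 were left out. The loess span in this step was 0.1, and spots entered it at a signal-to-noise score of at least 2. This linked 3064 of the 4100 genes, 74.7%, with a median difference of 0.010. All counts are over these 3064 genes, and every gene name comes from the authors' table; 3032 of the table's 4100 names were found in the reference gene table used for names. Links were checked by withholding values. Of 2544 genes linked on the acetate columns alone, 98.3% had the same nearest feature in the CCCP columns, with a median difference there of 0.0090 against 0.35 for a random feature. Of 2691 genes linked on the CCCP columns alone, 95.5% had the same nearest feature in the acetate columns, with a median difference of 0.011 against 0.36. Of 3538 decoy profiles, made by joining the acetate values of 1 gene to the CCCP values of another, 18 were linked (0.509%). Genes that changed little were linked less often: the median of the largest absolute log2 ratio was 0.89 in linked and 0.68 in other genes. The link uses the size of the ratios, so the linked genes are not a random sample of the genome.

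On genes linked without the acetate columns of 30 and 50 min, 10 of the 12 table columns fitted the arrays of their own sample best. These 10 had themselves made the links, so only the acetate columns of 30 and 50 min were tested. The acetate column of 30 min fitted the arrays filed under 50 min (r = 0.998) and the acetate column of 50 min those filed under 30 min (r = 0.999), both across genes, which are not independent replicates. The link set each column against the arrays it fitted, the comparisons used the order of the array files, and the other order was run as an alternative.

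Signals were corrected for background with limma's normexp method (offset 50), turned into log2 ratios and normalised within each array by loess, and the positions of a feature were averaged. Before the data were examined, normexp had been laid down for files without a corrected column; the files do hold one, but it is a plain subtraction floored at 0, so normexp stayed the main choice and that column, floored at 50, is an alternative. The offset draws ratios of dim spots towards 0, so values here can be smaller in size than the authors' (alsD with acetate: 4.78 here, 5.13 from the authors' table). No between-array scaling and no filter on dim spots was applied. One limma fit with 12 group means and an empirical Bayes spread held all 24 arrays (12 residual and 3.29 prior degrees of freedom). Each time was compared with the 0 min group of its series, so that a dye effect constant over time cancels. The main comparisons are the mean of 10 to 50 min for acetate, the same for CCCP, and the difference of both. Single times, 50 min against 10 min and 0 min against 0 were also tested. Every gene p is limma's, adjusted by the Benjamini-Hochberg method over the 3064 genes, and genes were called at an adjusted p below 0.05. Values are log2 changes with the standard error (SE) from this fit.

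Before the data were examined, 27 gene lists were fixed: the SigB, SigW and SigM stress regulons, LiaR and BceR, ribosomal proteins, purine and pyrimidine synthesis, branched-chain amino acids with CodY targets, the tricarboxylic acid cycle, acetate with acetoin and lactate metabolism, the respiratory chain, ATP synthase, fatty acid synthesis (FapR), heat shock, peroxide stress (PerR), thiol and quinone stress, iron uptake (Fur), sulfur assimilation, motility, competence, sporulation onset, carbon sources under catabolite repression, glycolysis with the PTS and pyruvate dehydrogenase, nitrogen metabolism, arginine synthesis, potassium with sodium and osmoprotectant transport, and the SOS response. One gene, yjbD, stands in 2 lists. Lists were tested with limma's camera against the other genes (preset correlation 0.01), with p adjusted over the 27 lists of a comparison, and again with an estimated correlation. Of 81 such tests 38 passed, and with an estimated correlation 3 passed, all in the difference of the treatments. Counts "adjusted over the list alone" adjust limma's p within the list. The genes named were set by a rule written before the data were examined. For acetate and for CCCP it takes the 10 largest increases and 10 largest decreases among called genes with the same sign on at least 9 of 10 arrays; for their difference the 6 largest each way; for 50 min against 10 min the 3 largest each way; and from each list up to 4 members with the smallest adjusted p. A gene named beyond this rule is said to be chosen after its values were seen.

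The pipeline was tested on simulated data with 200 genes changed out of 3064. In the acetate mean it recovered 26.9% of changes of 0.5, 80.6% of changes of 1 and 98.5% of changes of 2 on the log2 scale, with 2.14% false calls; at 10 min it recovered 8.96%, 65.7% and 98.5%, with 5.74% false calls. Simulated contrasts without change gave at most 1 call. Of 200 simulated lists without change, 6.5% had a camera p under 0.05. Simulated genes and arrays were drawn independently, while the real lists had estimated correlations of up to 0.848 (arginine synthesis). These rates therefore do not show how often calls of genes or lists are false in the real data.

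The alternatives fixed before the data were examined were no background correction, the scanner software's corrected signals, median centring without loess, scaling between arrays, only spots above background, no 0 min baseline, the replicate number as a fixed or a random block, the slide run as a block, only the arrays of the own series, an intensity trend with a robust prior, a minimum change of 1, leaving out each replicate, the deposited table's values, and an estimated camera correlation. Chosen after seeing the data were 5 more: the acetate 30 and 50 min arrays exchanged, both left out, all printed spots, differences within time and array number, and only the 2731 genes linked alike from each series. A slide run is a set of slides with neighbouring serial numbers; there were 4, runs 2 and 3 with the acetate arrays and runs 1, 3 and 4 with the CCCP arrays. Replicates are array numbers as the labels give them. R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used. No measured column of these samples was left out for its values.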

Results

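Each of the 12 samples (acetate or CCCP, at 0, 10, 20, 30, 40 or 50 min) was measured on 2 arrays from independent experiments. Median spot signals before background correction ran from 217.5 to 465.9 intensity units in the control channel and from 159.4 to 619.3 in the treated channel. Local backgrounds ran from 79.0 to 133.9 and from 65.6 to 152. A signal-to-noise score of at least 2 was reached by 70.9% to 87.3% of spots in the control channel and 68.2% to 83.3% in the treated channel. Acetate array 1 at 0 min held several of these extremes. It had the highest signal (619.3) and background (152) in the treated channel and the lowest share (70.9%) in the control channel. This array is 1 of the 2 behind every acetate change from 0 min. At most 107 spots of an array held pixels at the scanner's ceiling. The standard deviation between both arrays of a sample was 0.20 to 0.47 on the log2 scale. Across genes, which are not independent replicates, arrays of a sample correlated at r = 0.303 (CCCP at 30 min) to 0.782 (acetate at 10 min) after addition. At 0 min r was -0.098 with acetate and 0.057 with CCCP. Precision is limited by the number of arrays: the median SE was 0.20 for a mean over 5 times and 0.26 for a single time.

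At 0 min, before addition, limma called 0 of 3064 genes apart from the control culture in each series. At an unadjusted p under 0.05 there were 135 in the acetate and 33 in the CCCP series. All changes below are relative to these 0 min arrays.

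The first comparison asks which genes respond to acetate at pH 6.4. Acetate was added as its potassium salt, and no sample had that potassium added without acetate. Effects of acetate and of potassium therefore cannot be told apart. Over 10 to 50 min the strongest response was in the genes of acetoin synthesis: alsD (acetolactate decarboxylase) rose 27.4-fold, a log2 change of 4.78 ± 0.22 (SE, 2 arrays at each time; adjusted p = 1.25e-09). The gene alsS (acetolactate synthase) rose 21.4-fold (4.42 ± 0.17, adjusted p = 1.44e-10). The pyruvate dehydrogenase genes moved the other way: pdhB fell 6.18-fold (-2.63 ± 0.39, adjusted p = 0.00139), pdhC 5.37-fold (-2.42 ± 0.45, adjusted p = 0.00589) and pdhA 4.96-fold (-2.31 ± 0.24, adjusted p = 6.52e-05). Genes for the 2-oxoglutarate dehydrogenase complex of the tricarboxylic acid cycle rose, odhA by 1.36 ± 0.25 (adjusted p = 0.0059) and odhB by 1.34 ± 0.27 (adjusted p = 0.0106). Of the ribosomal protein, ATP synthase and fatty acid synthesis lists, 13 of 45, 2 of 9 and 7 of 15 genes fell; none of these list calls held, each with adjusted p = 0.107 with an estimated correlation. In all, 195 of 3064 genes changed, 67 up and 128 down. Each of the 20 genes named by size had the same sign on 10 of 10 arrays. The naming rule already required 9, and arrays of the same number share a 0 min array, so this is not separate support.

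Further increases by size were ykoJ at 3.36 ± 0.79 (adjusted p = 0.0215), yuiA at 1.82 ± 0.26 (adjusted p = 0.00114) and ybfA at 1.48 ± 0.36 (adjusted p = 0.0262). Smaller ones were amhX at 1.45 ± 0.29 (adjusted p = 0.00904), yuiB at 1.38 ± 0.19 (adjusted p = 0.001) and yxbC at 1.35 ± 0.30 (adjusted p = 0.0154). Further decreases were yoaB at -2.09 ± 0.32 (adjusted p = 0.00173), yfnA at -1.94 ± 0.37 (adjusted p = 0.00639) and yoaC at -1.71 ± 0.21 (adjusted p = 0.000323). The methionine transporter genes yusB and yusC fell by 1.84 ± 0.28 (adjusted p = 0.00153) and 1.83 ± 0.22 (adjusted p = 0.000323). Also lower were rplJ, for a ribosomal protein, at -1.64 ± 0.24 (adjusted p = 0.00114) and yxjH at -1.61 ± 0.22 (adjusted p = 0.000932).

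Of the 27 lists, 6 passed camera with acetate. Of 45 ribosomal protein genes 13 fell and 0 rose (27 fell when adjusted over the list alone), with a median of -0.84 (adjusted p = 1.21e-15). Among them rplL changed by -1.56, rpsE by -1.50 and rplU by -0.84. Of 15 genes in the fatty acid list 7 fell (8 adjusted over the list alone; median -0.88, adjusted p = 7.5e-07). Among them were fabHA (-1.32), fabF (-1.17) and fabD (-1.08) of fatty acid synthesis and plsX (-0.88) of phospholipid synthesis. Of 9 ATP synthase genes 2 fell, atpC (-0.89) and atpH (-0.74, lower on 9 of 10 arrays), and 7 when adjusted over the list alone (median -0.74, adjusted p = 0.000126). Of 13 tricarboxylic acid cycle genes 3 rose, odhA, odhB and sdhB (0.93, succinate dehydrogenase), and 7 when adjusted over the list alone (median 0.73, adjusted p = 1.16e-06). Of 12 genes of acetate, acetoin and lactate metabolism 3 rose and 1 fell, also when adjusted over the list alone (median 0.38, adjusted p = 0.000729). The 3 were alsS, alsD and acsA (1.15, acetyl-CoA synthetase, which uses acetate), and ackA (-0.86, acetate kinase, which forms it) fell. The SigB general stress list passed upward (median 0.22, adjusted p = 0.0011) with 0 of its 41 genes called, also when adjusted over the list alone. None of these calls held with an estimated correlation: that gave adjusted p = 0.879 for SigB and adjusted p = 0.107 for each of the other 5 with an estimated correlation.

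The other 21 lists did not pass (adjusted p from 0.057 to 0.942), but 7 of them held called genes. In glycolysis with the PTS and pyruvate dehydrogenase 5 of 16 fell and 1 rose (6 and 2 adjusted over the list alone). The genes pdhA, pdhB, pdhC, pdhD (-1.35) and ptsI (-0.86) of sugar uptake fell, and pgi (1.11, glucose-6-phosphate isomerase) rose. In sulfur assimilation, cysteine and methionine 7 of 30 fell (7 down and 1 up adjusted over the list alone; median -0.050), among them yusC, yusB, yxjH and yjcI (-1.45). In potassium, sodium and osmoprotectant transport nhaC (a sodium/proton antiporter) fell by 1.51 and opuCA and opuCB of a compatible solute importer rose by 1.07 and 0.99, also adjusted over the list alone. The other 28 of the 31 genes did not pass. Single genes were called in the respiratory chain (qoxD -0.69), competence (comGE 0.86), nitrogen metabolism (glnR -0.55) and branched-chain amino acid synthesis (ybgE 0.58; 3 adjusted over the list alone). The remaining 14 lists had 0 called genes, with medians from -1.07 (arginine synthesis, 9 genes with wide errors) to 0.17 (heat shock). In thiol and quinone stress the median (-0.026) and the test's sign (up, adjusted p = 0.942) differed, as they did for carbon sources (-0.0067, up) and potassium transport (-0.00082, up). The mean was below 0 for the first 2 and 0.038 for potassium transport.

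With acetate 478 genes were called at 10 min (183 up, 295 down) and 129 at 20 min (45 and 84). There were 70 at 30 min (16 and 54), 27 at 40 min (8 and 19) and 15 at 50 min (5 and 10). The time of the peak depends on the normalisation: scaling between arrays gave 76, 63, 7, 270 and 23 genes from 10 to 50 min, most at 40 min. Of 45 ribosomal protein genes 35 fell at 10 min (median -1.65), 13 at 20 min (-1.07) and 2 at 30 min (-0.79). All 9 ATP synthase genes fell at 10 min (median -1.76) and 0 passed from 20 min on. Purine synthesis had 13 of 19 genes lower at 10 min (median -1.51) and pyrimidine synthesis 6 of 10 (median -1.75), with 0 called in either at later times. The SigB list had 13 of 41 genes higher at 10 min (median 0.91) and 0 afterwards, with medians of 0.39 at 20 min and -0.078 at 40 min. While alsS was at 5.69 ± 0.22 at 10 min and 3.68 ± 0.22 at 50 min, pdhA stood at -0.54 ± 0.31 at 10 min (adjusted p = 0.256) and -2.41 ± 0.31 at 20 min (adjusted p = 0.000591). Between 10 and 50 min 304 genes changed, 205 up and 99 down, a balance that turned without acetate replicate 1 (49 up, 70 down) or replicate 2 (6 up, 10 down). The largest increases were the pyrimidine and purine genes pyrF (3.61 ± 0.58, adjusted p = 0.00154), pyrAB (3.10 ± 0.58, adjusted p = 0.00436) and purH (3.0 ± 0.54, adjusted p = 0.00352). The largest decreases were argJ of arginine synthesis (-3.96 ± 1.07, adjusted p = 0.0303) and the histidine synthesis genes hisZ (-3.89 ± 0.38, adjusted p = 7.54e-05) and hisB (-3.80 ± 0.46, adjusted p = 0.000158). If the 30 and 50 min arrays stood in the order of the authors' table, the counts would be 15 at 30 min, 70 at 50 min and 155 between 10 and 50 min (73 up, 82 down). Leaving out 1 of the 4 replicates in turn gave 35 to 476 genes at 10 min, 7 to 129 at 20 min and 5 to 60 at 30 min. It gave 4 to 11 at 40 min, 3 to 19 at 50 min and 16 to 338 between 10 and 50 min.

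Calls for acetate rested on both array numbers: without acetate replicate 1 or 2 there were 17 and 11 called genes (7 up and 4 down without replicate 2), including 9 and 7 of the 20 named by size, with 0 of the 20 changing sign. At 0 min acetate array 1 lay in slide run 2 and array 2 in run 3, the reverse of every later time, so it is not known that a number marks the same experiment throughout. Leaving out a replicate and every split by array number depend on this. Without CCCP replicate 1 or 2, which enter only through the spread, 18 of the 20 passed, all but ybfA and ykoJ. With the slide run as a block 166 genes passed. Within runs 2 and 3 the changes were 4.50 and 4.35 for alsS, -2.53 and -2.08 for pdhA and -1.50 and -1.77 for rplJ. They lay further apart for ykoJ (4.74 and 1.97), yfnA (-3.27 and -0.62), ybfA (2.28 and 0.68), yuiA (1.19 and 2.46), yxbC (1.72 and 0.98), pdhB (-3.32 and -1.94) and pdhC (-3.09 and -1.76). List medians there were -1.07 and -0.62 for ribosomal proteins, -0.67 and -0.76 for ATP synthase and -1.26 and -0.56 for fatty acid synthesis. They were 0.99 and 0.44 for the tricarboxylic acid cycle, 0.36 and 0.30 for acetate and acetoin, and 0.41 and 0.054 for SigB. The balance of directions depends on the normalisation: median centring without loess moved the median of all genes by -0.24, and 12 genes were then called up and 231 down, with odhA and odhB no longer called. At single times it gave 66 up and 452 down at 10 min and 10 and 66 at 20 min. Later it gave 5 and 109 at 30 min, 2 and 21 at 40 min, and 2 and 14 at 50 min. Scaling between arrays gave 142 up and 128 down at 40 min.

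**Figure D1:**
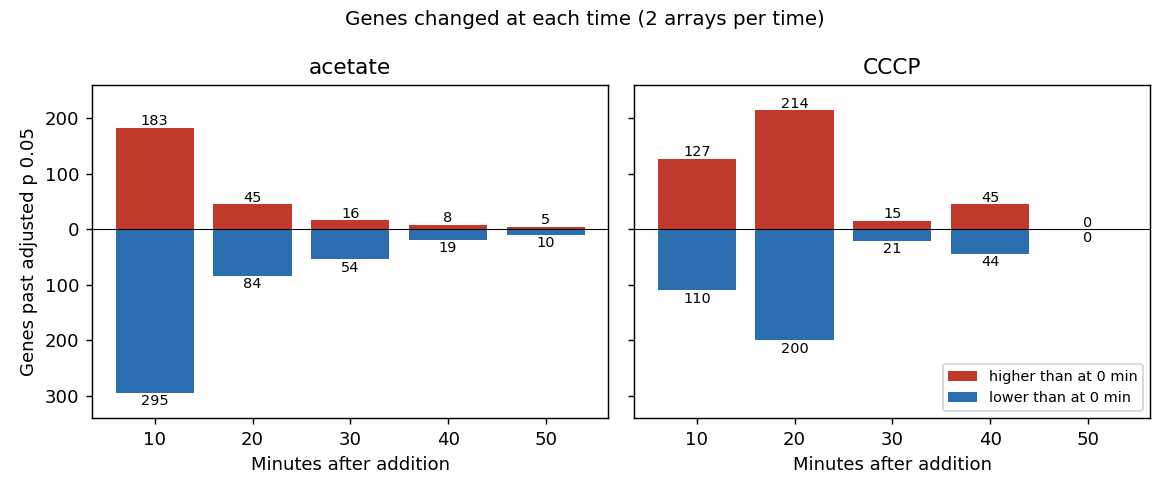
Bars count genes past limma's adjusted p of 0.05 against 0 min (y axis, number of genes; higher above the line, lower below it) at each time in minutes after addition (x axis), for acetate and CCCP, with 2 arrays per time. Counts peak at 10 min with acetate (183 higher, 295 lower) and at 20 min with CCCP (214 higher, 200 lower); median centring without loess gives 66 higher and 452 lower at 10 min with acetate, scaling between arrays puts the acetate peak at 40 min (270 genes against 76 at 10 min), and with CCCP the scanner software's signals (371 against 283), the slide run as a block (230 against 201) and scaling (172 against 1) give more genes at 10 than at 20 min.

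The second comparison asks which genes respond to CCCP, a protonophore. The largest increases included genes of the lev operon for fructose uptake and levan use: levG rose 4.79-fold (2.26 ± 0.30, 2 arrays at each time; adjusted p = 0.00149) and levE by 2.19 ± 0.30 (adjusted p = 0.00149). In the same operon levD rose by 2.10 ± 0.29 (adjusted p = 0.00149), levF by 2.03 ± 0.29 (adjusted p = 0.00151) and sacC (levanase) by 1.88 ± 0.27 (adjusted p = 0.00149). The glycerol genes glpF (uptake) and glpK (kinase) rose 3.39-fold (1.76 ± 0.30, adjusted p = 0.00556) and 3.08-fold (1.62 ± 0.27, adjusted p = 0.00494). Genes of the yxi cluster fell, among them yxiJ 2.67-fold (-1.42 ± 0.20, adjusted p = 0.00149). In all 98 of 3064 genes changed, 47 up and 51 down (a balance that differed between fits, given below), and each of the 20 genes named by size had the same sign on 10 of 10 arrays.

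Other increases by size were ydaO, a potassium importer gene, at 2.12 ± 0.52 (adjusted p = 0.0375), bglH (a phospho-beta-glucosidase) at 1.68 ± 0.39 (adjusted p = 0.0294) and prsA (an extracellular foldase) at 1.51 ± 0.33 (adjusted p = 0.0219). The largest decreases were yodF at -1.80 ± 0.32, yxzC at -1.78 ± 0.32 and aroA, of aromatic amino acid synthesis, at -1.78 ± 0.32, each with adjusted p = 0.00654. Next came yxxG at -1.59 ± 0.40 (adjusted p = 0.0394), yxiH at -1.58 ± 0.34 (adjusted p = 0.0202) and yoaB at -1.48 ± 0.32 (adjusted p = 0.0216). Lower to a similar degree were ybgF at -1.45 ± 0.25 (adjusted p = 0.00654), yxiG at -1.40 ± 0.35 (adjusted p = 0.0401) and yxiF at -1.38 ± 0.27 (adjusted p = 0.00852).

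Of the 27 lists, 16 passed camera with CCCP, and 0 of these held with an estimated correlation. Of 34 genes for carbon sources under catabolite repression 12 rose and 0 fell (20 adjusted over the list alone; median 0.66, adjusted p = 3.01e-14, adjusted p = 0.285 with an estimated correlation). Beyond those above, rbsB of ribose uptake changed by 1.26 and glpD of glycerol use by 1.09. Of 45 ribosomal protein genes 2 fell, rplJ (-1.07) and rplA (-0.72), and 8 adjusted over the list alone (median -0.52, adjusted p = 9.2e-10). Of 24 genes of branched-chain amino acid synthesis and CodY targets 2 fell, yhdG (-1.15, uptake) and ilvD (-0.94), and 10 adjusted over the list alone (median -0.54, adjusted p = 6.57e-07). Purine synthesis passed downward with 0 of 19 genes called and 4 adjusted over the list alone (median -0.56, adjusted p = 3.99e-05). Of 13 tricarboxylic acid cycle genes 1 rose, sucD (1.06, succinyl-CoA ligase), and 5 adjusted over the list alone (median 0.55, adjusted p = 5.04e-05). Of 16 glycolysis, PTS and pyruvate dehydrogenase genes 1 rose, pgi (0.93), and 3 adjusted over the list alone (median 0.41, adjusted p = 9.9e-05). For each of these 5 lists it was also adjusted p = 0.285 with an estimated correlation.

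Further lists passed. The SigM envelope stress list passed upward with 0 of 15 genes called, also over the list alone (median 0.53, adjusted p = 0.00376; adjusted p = 0.597 with an estimated correlation). The SigW list passed downward with 0 of 41 (median -0.18, adjusted p = 0.00376; adjusted p = 0.429 with an estimated correlation). In the respiratory chain 1 of 17 genes rose, qcrC (1.12, cytochrome bc complex), and 4 adjusted over the list alone (median 0.35, adjusted p = 0.00376; adjusted p = 0.429 with an estimated correlation). In potassium, sodium and osmoprotectant transport 2 of 31 fell, nhaC (-0.87) and opuBA (-0.72), and over the list alone 7 fell and 1 rose (median -0.20, adjusted p = 0.00376; adjusted p = 0.285 with an estimated correlation). Thiol and quinone stress had 2 of 25 higher, hxlA (1.23, higher on 9 of 10 arrays) and yqiG (1.16, on 8 of 10), also over the list alone (median 0.16, adjusted p = 0.024; adjusted p = 0.542 with an estimated correlation). In sulfur assimilation yxjH fell (-0.96) and ytmI rose (0.51), with 4 down and 1 up of 30 adjusted over the list alone (median -0.19, adjusted p = 0.0405; adjusted p = 0.299 with an estimated correlation). Iron uptake (median -0.26, adjusted p = 0.00406) and motility (-0.12, adjusted p = 0.0207) passed downward with 0 genes called, as did arginine synthesis (-1.03, adjusted p = 0.0405), also over the list alone. Their medians turned over time: iron uptake was at 0.25 and 0.20 at 10 and 20 min and -0.37, -0.78 and -0.52 from 30 to 50 min. Motility was at -0.64, -0.57 and -0.18 from 10 to 30 min and 0.34 and 0.19 at 40 and 50 min, and arginine synthesis went from -2.31 at 10 min to 0.83 at 40 min. Heat shock passed upward (0.20, adjusted p = 0.0149) with 0 called and 3 adjusted over the list alone. With an estimated correlation iron uptake, motility, arginine synthesis and heat shock gave adjusted p = 0.597, adjusted p = 0.733, adjusted p = 0.703 and adjusted p = 0.542.

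Among the 11 lists that did not pass with CCCP (adjusted p from 0.19 to 0.868), 2 held a called gene. Acetate, acetoin and lactate metabolism had 1 of 12 genes higher, acsA (1.49), and fatty acid synthesis 1 of 15 lower, des (-0.81, a membrane lipid desaturase), both also over the list alone. The other 9 had 0 called genes: SigB (median 0.091), LiaR and BceR (-0.22), pyrimidine synthesis (-0.044), ATP synthase (0.16), peroxide stress (-0.039), competence (-0.14), sporulation onset (-0.057), nitrogen metabolism (-0.050, with 2 of 16 lower over the list alone) and the SOS response (0.017). For peroxide stress the mean (0.015) and the test were positive against a negative median, and for nitrogen metabolism the mean (0.0056) was positive against a negative median and test.

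With CCCP 237 genes were called at 10 min (127 up, 110 down) and 414 at 20 min (214 and 200). There were 36 at 30 min (15 and 21) and 89 at 40 min (45 and 44). At 50 min limma called 0, with 183 genes at an unadjusted p under 0.05. This 0 depends on the fit: the replicate number as a fixed block gave 13 and as a random block 8. Scaling between arrays gave 13 and the scanner software's signals 1. More genes were called at 10 than at 20 min with the scanner software's signals (371 and 283), with the slide run as a block (230 and 201) and with scaling between arrays (172 and 1). Carbon source genes stood higher in 21 of 34 cases at 10 min (median 1.13), 18 at 20 min (1.07), 8 at 30 min, 6 at 40 min and 0 at 50 min. Purine genes were lower in 12 of 19 cases at 10 min (median -1.44) and at 20 min (-1.61), and in 0 from 30 min on. Ribosomal protein genes were lower in 18 of 45 cases at 10 min (median -1.23) and 12 at 20 min (-0.83). The SigM list had 1 of 15 genes higher at 10 min (median 1.12) and 4 at 20 min (1.36). At 50 min some medians had the other sign than the mean, as in SigM (-0.15), heat shock (-0.21), thiol stress (-0.14), purines (0.33) and potassium transport (0.036). Between 10 and 50 min 233 genes changed, 99 up and 134 down (31 and 110 without CCCP replicate 1, 21 and 63 without replicate 2). The largest increases were the purine genes purA (2.35 ± 0.47, adjusted p = 0.00746) and purC (2.20 ± 0.46, adjusted p = 0.00989) and ribE of riboflavin synthesis (2.28 ± 0.33, adjusted p = 0.00142). The largest decreases were rbsB of ribose uptake (-3.24 ± 0.31, adjusted p = 7.77e-05) and licH and licA of lichenan use (-3.22 ± 0.61, adjusted p = 0.0063, and -3.02 ± 0.73, adjusted p = 0.021). Leaving out 1 of the 4 replicates in turn gave 71 to 162 genes at 10 min, 155 to 275 at 20 min and 2 to 57 at 30 min. It gave 16 to 19 at 40 min, 0 at 50 min and 84 to 141 between 10 and 50 min. Without CCCP replicate 1 or 2 calls leaned upward at 10 min (109 up and 53 down, 56 and 15), and without replicate 2 also at 20 min (69.8% up).

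Without CCCP replicate 1 or 2 there were 55 (44 up, 11 down) and 98 called genes (76 up, 22 down), with 13 and 14 of the 20 named by size. Without either acetate replicate, which enters only through the spread, there were 35 and 10 of the 20. The calls of levD to levG, sacC, glpF and yxiJ held without any 1 of the 4 replicates. List calls were also lost without CCCP replicate 1 for heat shock (median 0.19), iron uptake (-0.097) and motility (0.046, the other sign). They were lost without CCCP replicate 2 for sulfur assimilation (-0.10) and potassium transport (-0.076), and without either for arginine synthesis (-1.11 and -1.06). With the slide run as a block 60 genes passed (21 up, 39 down) and bglH, prsA, ydaO, yxiG and yxxG lost their calls. Within run 1, which held only the 10 min array beside its 0 min array, and run 4 the changes were 2.00 and 2.37 for levG, 1.35 and 2.08 for glpF and -1.05 and -1.61 for yxiJ. They lay further apart for yoaB (-0.59 and -2.01), yxiG (-0.47 and -1.69), prsA (0.90 and 1.81), yodF (-1.13 and -2.01) and ydaO (3.90 and 2.32). The 2 arrays in run 3 had no 0 min partner in this series. List medians in runs 1 and 4 were 0.93 and 0.64 for carbon sources, -0.91 and -0.52 for ribosomal proteins and -0.55 and -0.70 for branched-chain amino acids. They were -1.48 and -0.81 for purines, 0.65 and 0.75 for the tricarboxylic acid cycle, 0.78 and 0.45 for glycolysis and 1.45 and 0.56 for SigM. Further medians were -0.12 and -0.28 for SigW, 0.32 and 0.38 for the respiratory chain, 0.60 and 0.28 for heat shock, and 0.10 and 0.18 for thiol stress. Motility was at -0.57 and -0.23, arginine synthesis at -3.67 and -1.36 and sulfur assimilation at -0.29 and -0.39. The iron list was at 0.30 and -0.13 and potassium transport at 0.042 and -0.27, so their direction did not hold in both; run 1 holds only 10 min, when iron uptake over both arrays was at 0.25. Scaling between arrays left 29 genes in the mean, with 9 of the 20 named by size; levF, glpF and glpK were among those lost. Median centring without loess ended the calls of prsA, ydaO and yxxG. It gave 45 up and 31 down in the mean, 118 and 12 at 10 min and 20 and 2 at 30 min. There were 11 and 27 at 40 min and 11 and 203 for 50 against 10 min. Scaling between arrays gave 113 up and 59 down at 10 min.

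**Figure D2:**
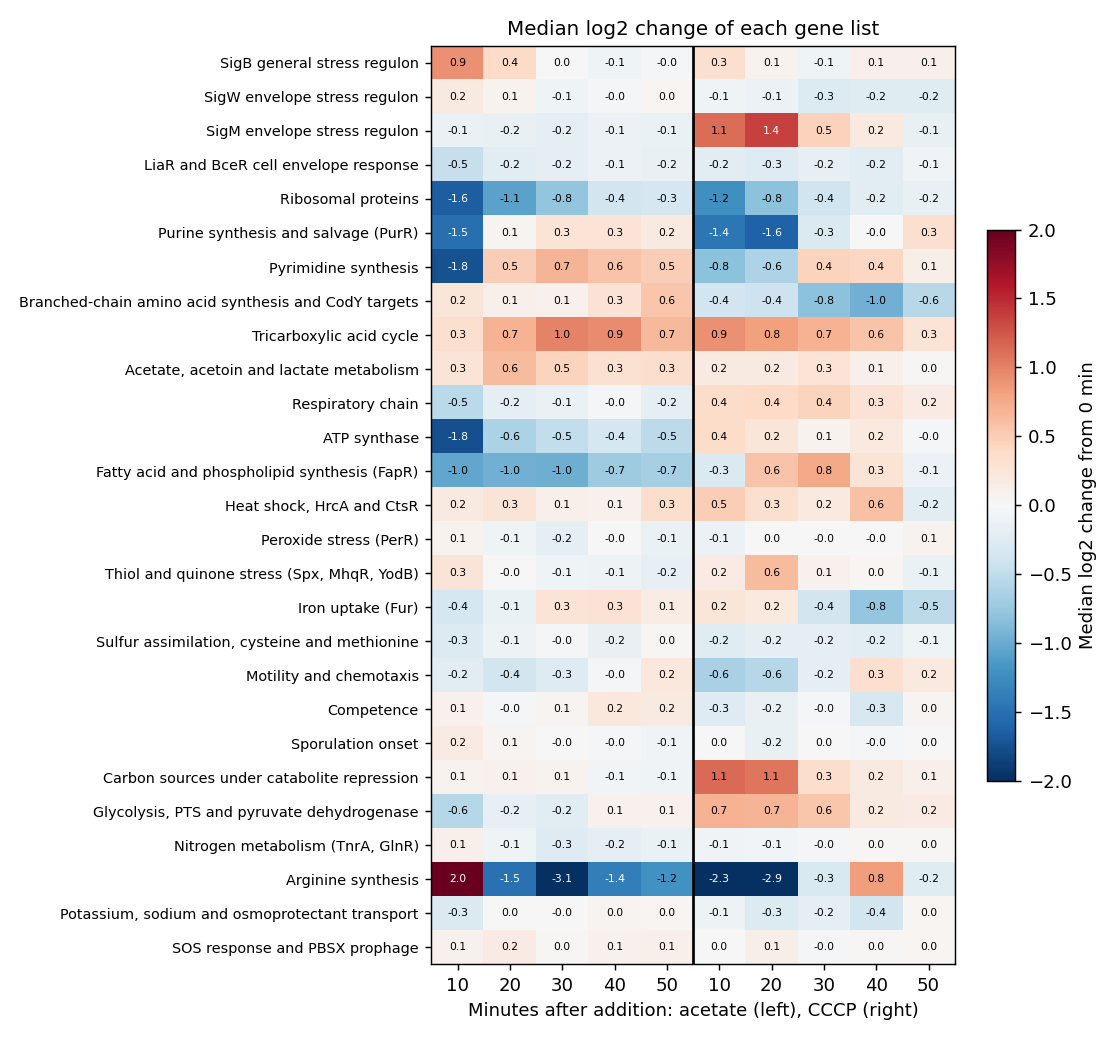
Each cell gives the median log2 change from 0 min of a gene list (y axis, 27 lists) at a time in minutes after addition (x axis; acetate left, CCCP right), with colours capped at 2 in either direction. Carbon sources reach 1.13 at 10 min with CCCP against 0.073 with acetate, and ATP synthase genes reach -1.76 at 10 min with acetate against 0.37 with CCCP.

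The third comparison asks where acetate and CCCP differ, tested as the difference of their changes. Potassium was added with acetate and not with CCCP, so the difference includes any effect of it. Acetoin synthesis stood higher with acetate: alsD differed by 5.17 ± 0.32 (adjusted p = 6.23e-08) and alsS by 4.71 ± 0.24 (adjusted p = 9.62e-09), with CCCP values of -0.40 and -0.29. Pyruvate dehydrogenase stood lower with acetate. The gene pdhB differed by -3.55 ± 0.55 (adjusted p = 0.00784) and pdhC by -3.44 ± 0.64 (adjusted p = 0.0219). The difference was -3.21 ± 0.34 for pdhA (adjusted p = 8.01e-05) and -2.02 for pdhD (adjusted p = 0.0367). With CCCP alone pdhB, pdhC, pdhA and pdhD were at 0.92, 1.02, 0.91 and 0.66, each short of limma's threshold. Glycerol and levan genes were lower with acetate than with CCCP, with differences of -2.59 ± 0.42 for glpF (adjusted p = 0.00784), -2.30 ± 0.38 for glpK (adjusted p = 0.00844) and -2.18 ± 0.42 for levG (adjusted p = 0.0226). The calls of glpF and levG did not hold for differences taken within time and array number, an alternative chosen after the data were seen. In all 26 of 3064 genes differed, 12 higher and 14 lower with acetate. Also higher with acetate were yuiA (2.31 ± 0.37, adjusted p = 0.00784), amhX (2.05 ± 0.41, adjusted p = 0.0236) and opuCC and opuCA of the compatible solute importer (1.95 ± 0.42, adjusted p = 0.0417, and 1.93 ± 0.43, adjusted p = 0.0437).

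In this difference 16 of 27 lists passed, and 3 held with an estimated correlation. These were ATP synthase (median -0.86, adjusted p = 2.36e-06), fatty acid synthesis (-1.18, adjusted p = 2.61e-07) and glycolysis with the PTS and pyruvate dehydrogenase (-0.55, adjusted p = 1.97e-07), each lower with acetate and each with adjusted p = 0.0499 with an estimated correlation. In these, 0 of 9, 0 of 15 and 4 of 16 genes differed (0, 6 and 5 adjusted over the list alone), the 4 being pdhA to pdhD. Carbon source genes were lower with acetate than with CCCP (7 of 34 genes, 14 adjusted over the list alone, median -0.55, adjusted p = 2.44e-12; adjusted p = 0.149 with an estimated correlation), levD among them at -2.11. Branched-chain amino acid genes were higher (1 of 24, ybgE at 1.15, also over the list alone; median 0.84, adjusted p = 3.27e-12; adjusted p = 0.137 with an estimated correlation). The respiratory chain was lower (0 of 17, median -0.67, adjusted p = 1.64e-06; adjusted p = 0.149 with an estimated correlation), as was SigM (0 of 15, -0.85, adjusted p = 0.000758; adjusted p = 0.572 with an estimated correlation). Potassium, sodium and osmoprotectant transport passed upward with 3 of 31 genes higher, opuCC, opuCA and opuBA (1.02), and 7 adjusted over the list alone (median 0.037, adjusted p = 0.00885; adjusted p = 0.323 with an estimated correlation). Acetate, acetoin and lactate metabolism passed upward on alsS and alsD, the 2 of 12 that differed, also over the list alone (mean 0.67, adjusted p = 0.0422; adjusted p = 0.323 with an estimated correlation), against a negative median of -0.049.

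Lists with 0 genes apart in the difference, also over the list alone, passed upward for SigW (median 0.19, adjusted p = 0.000194), iron uptake (0.27, adjusted p = 0.000544), purine synthesis (0.44, adjusted p = 0.00111), competence (0.19, adjusted p = 0.0105) and SigB (0.16, adjusted p = 0.0405). They passed downward for ribosomal proteins (-0.27, adjusted p = 0.0212) and thiol stress (-0.13, adjusted p = 0.0403). With an estimated correlation these gave, in that order, adjusted p = 0.305, adjusted p = 0.533, adjusted p = 0.323, adjusted p = 0.491, adjusted p = 0.798, adjusted p = 0.693 and adjusted p = 0.572. Median centring without loess moved the median of all genes in the difference by -0.24. The medians of SigB (-0.027), SigW (-0.073), iron uptake (-0.013), competence (-0.043) and potassium transport (-0.037) were then below 0 but above that of all genes, and these lists still passed upward (adjusted p from 0.00159 to 0.0254). The other 11 lists did not pass (adjusted p from 0.37 to 0.69) and had 0 genes apart, with 2 of 30 lower in sulfur assimilation when adjusted over the list alone.

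Scaling between arrays ended every call of a gene in this difference, leaving 0 of 26. Without acetate replicate 1 or 2 there were 4 and 5 genes, and without CCCP replicate 2 there were 27 (7 higher, 20 lower with acetate). With acetate replicate 1 or 2 left out 3 and 4 of the 12 named by size passed. Without CCCP replicate 1 or 2 the named genes passing were 7 and 8 of 12. Of these 12 only alsD and alsS passed without each of the 4 replicates in turn. Median centring without loess called 4 genes higher and 15 lower and ended the calls of opuCA, opuCC and pdhC. List calls were lost without acetate replicate 1 for iron uptake (median 0.15), competence (0.050) and acetate and acetoin (-0.043), and without acetate replicate 2 for SigB (0.0075), ribosomal proteins (-0.21), purines (0.20) and thiol stress (-0.13). They were lost without CCCP replicate 1 for SigB (0.11) and acetate and acetoin (-0.13), and without CCCP replicate 2 for ribosomal proteins (-0.25), competence (0.020), acetate and acetoin (0.063) and potassium transport (-0.037). With the slide run as a block 18 genes passed, without levG, opuCA and opuCC. Differences within time and array number, meant for control RNA that may have been used in both series, gave 15 genes (9 higher, 6 lower). They kept 10 of the 12, without glpF and levG. The treatments share only slide run 3, where CCCP has no 0 min array, so no within-run difference could be had.

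**Figure D3:**
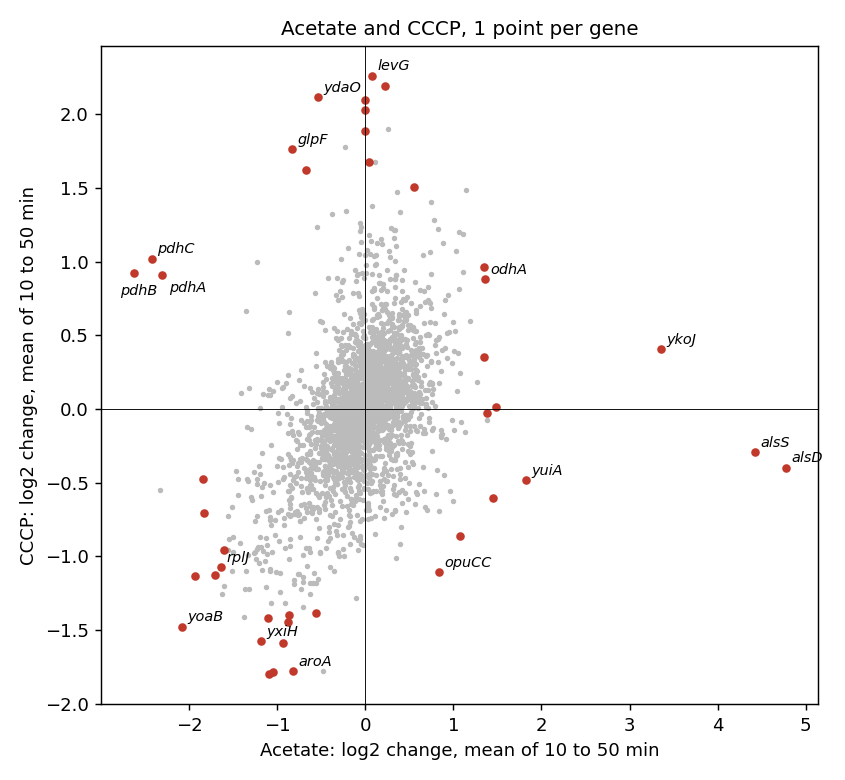
Each point is 1 of 3064 genes, by its log2 change with acetate (x axis) and with CCCP (y axis), mean of 10 to 50 min; red points are genes named by size in a main comparison. The genes alsS (4.42, -0.29) and pdhB (-2.63, 0.92) lie far from the diagonal, and yoaB (-2.09, -1.48) lies near it.

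Some genes were called with both treatments: 4 were higher in both and 27 lower in both, with 0 in opposite directions. Independent lists of these lengths would have 1.03 and 2.13 in common. In 100 simulations of unchanged groups with the same controls, added after the overlap was seen, 0 genes were called in both, and lists as long as the real ones, taken by rank, had 9.45 (4 to 17) of the highest and 14.7 (8 to 23) of the lowest genes in common. The values for independent lists leave out any shared controls and the simulated ones the effects, so part of the overlap may come from the controls. The 4 were acsA (1.15 with acetate, 1.49 with CCCP), pgi (1.11, 0.93), kduI (0.73, 0.73) and yraK (0.62, 0.81); kduI and yraK are named for the small count, after their values were seen. Among the 27 were nhaC (-1.51, -0.87), the ribosomal protein genes rplJ (-1.64, -1.07) and rplA (-0.84, -0.72), the desaturase gene des (-0.53, -0.81), yoaB (-2.09, -1.48) and yoaC (-1.71, -1.12). Across genes, which are not independent replicates, the changes correlated at r = 0.429 (Spearman's rho 0.464). The control channels matched by time between the series, as control RNA used in both would give. Arrays of the same time and number from both series had a mean r of 0.52 across genes in their Cy3 profiles, against 0.348 over permuted times (one-sided permutation p = 1e-05, the smallest that 100000 permutations can give). Of the 12 acetate arrays, 8 matched the CCCP array of their own time and number best. Times were permuted within array number, so this does not tell shared RNA from separate control cultures sampled at the same times. Between arrays of different number the mean r was also higher at the same time (-0.357) than at other times (-0.424). Shared control alone, simulated with no change and 50% of the array variance from the control, gave r = 0.501 with 66.7% of genes of like sign, against 67.7% measured. The simulated r follows from the 50% set and from leaving out all effects, as does the simulated share of like sign. Neither therefore decides whether the measured values exceed what a shared control gives. In covariance, which keeps the size of the changes, the measured value was 0.079 against 0.029 simulated. A shared control at this setting thus gave less covariance than was measured. Between arrays of different number, which would have different controls if RNA was shared by number, r was 0.293. It was 0.406 for the same number and 0.621 between replicates of a treatment. Acetate array 1 showed no gap, with 0.373 for the different and 0.371 for the same number. For acetate array 2 these were 0.213 and 0.44.

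**Figure D4:**
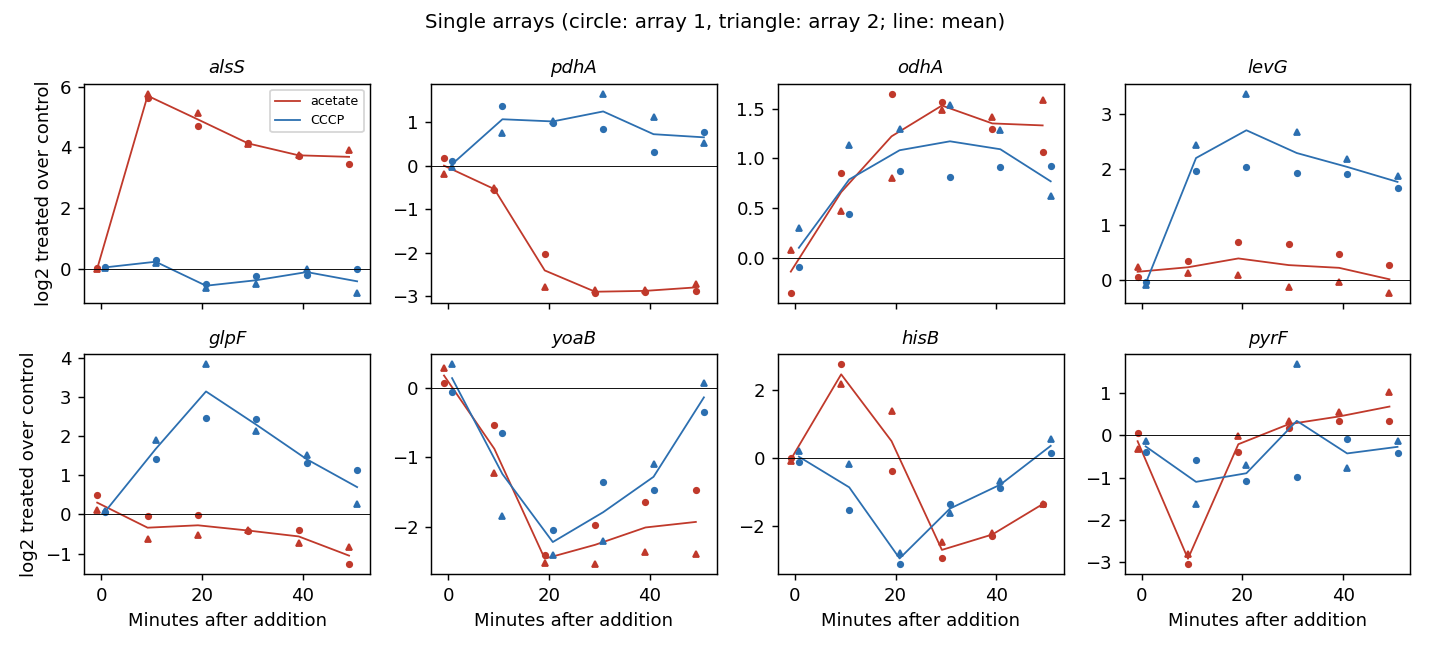
Log2 ratio of treated over control (y axis) on single arrays (circles, array 1; triangles, array 2; lines, mean) by minutes after addition (x axis), for 8 genes, with acetate in red and CCCP in blue. With acetate alsS changed by 5.69 at 10 min and pyrF by -2.79, while hisB changed by 2.49 at 10 min and -2.65 at 30 min.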

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

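The tests of the time order, of slide runs, of dye bias and of the control channel's ribosomal messages below were chosen after the result was seen; the other tests on ribosomal protein genes and the splits of the time courses were written before it.

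Differences between times and between treatments stood out by limma's test of the difference itself. Between 10 and 50 min 304 genes differed with acetate and 233 with CCCP, and between acetate and CCCP 26 genes differed.

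With acetate the genes that rose most from 10 to 50 min were pyrF by 3.61, pyrAB by 3.10 and purH by 3.0, and those that fell most were argJ at -3.96, hisZ at -3.89 and hisB at -3.80. With CCCP they were purA at 2.35, ribE at 2.28 and purC at 2.20, and downward rbsB at -3.24, licH at -3.22 and licA at -3.02.

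Between acetate and CCCP the genes higher with acetate were alsD (5.17), alsS (4.71), yuiA (2.31), amhX (2.05), opuCC (1.95) and opuCA (1.93). Those lower were pdhB (-3.55), pdhC (-3.44), pdhA (-3.21), glpF (-2.59), glpK (-2.30) and levG (-2.18). Of 16 lists that passed camera's test of the difference, fatty acid synthesis, ATP synthase and glycolysis also passed with an estimated correlation (adjusted p = 0.0499 each); for the other 13 it was adjusted p = 0.137 to 0.798. Calls of SigB, ribosomal proteins, purines, acetate and acetoin, thiol stress, iron uptake, competence and potassium transport were also lost without 1 of the replicates. Median differences were positive for branched-chain amino acids (0.84), purines (0.44), iron uptake (0.27), SigW (0.19), competence (0.19), SigB (0.16) and potassium transport (0.037). They were negative for fatty acid synthesis (-1.18), ATP synthase (-0.86), SigM (-0.85), the respiratory chain (-0.67), carbon sources (-0.55), glycolysis (-0.55), ribosomal proteins (-0.27), thiol stress (-0.13) and acetate and acetoin metabolism (-0.049, with a test in the upward direction). The arrays form 4 time courses, which can be split in 3 ways; these splits are too few for a share under 0.05. The real split gave 26 genes and the highest of the others 0, so 1 of the 3 gave as many. The other splits join an acetate with a CCCP time course, so a treatment difference cancels in them and widens their spread. Their count of 0 is therefore no separate support.

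The genes of pyruvate dehydrogenase fell and those of acetoin synthesis rose with acetate. A run of slides carrying the change is argued against: the medians were -3.09 and 4.70 in run 2 and -1.94 and 4.50 in run 3, the smallest of them 1.94 in size. A dye bias constant over time cancels in the baseline, so the 0 min ratios do not test it. A difference between the cultures before addition, as the source of these changes, is argued against as well. The largest mean 0 min ratio of the 5 genes was 0.171 in size (pdhC, -0.17). The SD between both 0 min arrays was 0.57 for pdhC and 0.609 for pdhB, below the changes in either run. The response to acetate itself, which the design gives as the biological explanation, stays open as a hypothesis that was found and tested on the same data.

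The medians of ribosomal protein genes were below 0 with both treatments; the list calls were lost with an estimated correlation (adjusted p = 0.107 with acetate and adjusted p = 0.285 with CCCP). In the difference 0 of 45 genes passed, and the list call was lost with an estimated correlation (adjusted p = 0.693) and without acetate replicate 2 or CCCP replicate 2. Bright spots drawn down by the normalisation are argued against. The median over lists matched on signal was -0.0288 for acetate and -0.0595 for CCCP, against -0.84 and -0.52. Of 10000 matched lists 0 percent had a median as low, and the lowest were -0.47 and -0.45. The matched lists hold no genes regulated together, so this share does not measure how rare such a list is. A single control culture rich in these messages would leave 1 of the array numbers near 0, but the 4 medians by treatment and array number were -0.79, -0.83, -0.46 and -0.59, the highest being -0.455. By slide run, which crosses the acetate numbers at 0 min, they were -1.07 and -0.62 with acetate. A rise of these messages after 0 min in the control cultures of both array numbers would lower all 4 and stays open. Median control channel changes of the list were 0.862 and 0.0648 for acetate arrays 1 and 2 and 0.107 and 0.097 for CCCP. In the treated channel they were -0.026, -0.711, -0.204 and -0.437, so in 3 of the 4 the treated channel fell by more than the control rose, which counts against a control rise as the whole cause there. It is not excluded, since a channel alone is compared between slides, where a difference between slides moves both channels, and each value rests on a single 0 min array. A slower growth of treated cultures was not tested and stays open, as does a response to each compound.

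The acetate columns of 30 and 50 min in the authors' table hold the arrays filed under 50 and 30 min, which bears on the 50 against 10 min results. Exchanged times in the array files are argued against: control channels correlated better across genes with the CCCP control of the same filed time than with that of the exchanged time, by 0.0995 on average and in 4 of 4 arrays (0.041 to 0.16). Files and table give opposite orders, so an argument against exchanged files speaks for exchanged columns in the table. A separate prediction for the columns was not met in full, so the order is not settled. The 20 min arrays lay nearer to those filed under 30 min on average (r = 0.734 against 0.557 across genes, a difference of 0.178). They did so in 4 of 4 comparisons between arrays of like number. The prediction asked that each correlation with 30 min exceed each with 50 min, and the ranges of single-array correlations overlapped.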

How the results depend on the processing

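The following alternatives were chosen after the data had been seen: acetate 30 and 50 min exchanged, these times left out, all printed spots, differences within time and array number, and only genes linked the same way from each series alone. Every alternative fixed before the data were examined was run; the authors' table has no test. Counts are of genes past the adjusted threshold, and except where stated the cause was not tested.

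Without the 0 min baseline the counts were 1480 in the acetate mean and 1079, 484, 380, 123 and 162 from 10 to 50 min. The baseline takes out a dye effect constant over time, but leaving it out also drops the error of the 0 min arrays. More genes can pass for either reason, and these were not told apart. At 0 min itself 0 genes were called in each series. For CCCP they were 1626 in the mean and 758, 1159, 337, 611 and 68 by time, with 806 in the difference and r = 0.486 across genes. Without background correction there were 27 genes at 50 min (acetate) and 46 at 40 min (CCCP). The scanner software's signals gave 371 at 10 min and 1 at 50 min with CCCP.

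Median centring gave 76 and 114 genes at 20 and 30 min and 94 for 50 against 10 min with acetate, 130, 237, 22 and 38 from 10 to 40 min with CCCP, and r = 0.510. Scaling between arrays gave 76, 63, 7, 270 and 23 from 10 to 50 min and 57 for 50 against 10 min with acetate. For CCCP it gave 29 in the mean, 1, 0, 2 and 13 from 20 to 50 min and 2 at 0 min, with 0 in the difference and r = 0.321. A minimum change of 1 can only lower a count: it left 76, 295 at 10 min and 194 for 50 against 10 min with acetate, and 54, 258 at 20 min and 57 at 40 min with CCCP.

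The replicate number as a block gave 223, 130 and 75 genes at 20, 30 and 50 min with acetate. With CCCP it gave 232 in the mean, 365, 69, 185 and 13 at 10, 30, 40 and 50 min and 358 for 50 against 10 min, with 48 in the difference. Deviations of same-numbered arrays correlated at r over 0.1 in 14 of 15 pairs of times with acetate (lowest 0.062, median 0.272) and in 9 of 15 with CCCP (lowest -0.36, median 0.164). As not every pair did, the numbers were not taken as pairs and these counts are not used for the main results. The correlations are a hint from the data, not the design. A further hint came from Cy3 profiles of arrays from different series and times. Their mean r across genes was 0.313 for the same number and -0.424 for different numbers. As a random block (correlation 0.149) the replicate number gave 197, 121 and 55 at 20, 30 and 50 min with acetate. With CCCP it gave 224, 69, 162 and 8 (mean, 30, 40 and 50 min), with 40 in the difference. The slide run as a block gave 33 at 50 min with acetate, 60 in the mean, 201, 12 and 30 from 20 to 40 min and 66 for 50 against 10 min with CCCP, and r = 0.374.

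Fitting a series alone, with fewer arrays, gave 11 at 40 min with acetate, and 35 in the mean, 100, 155, 2 and 16 from 10 to 40 min and 93 for 50 against 10 min with CCCP. The trend with a robust prior gave 83, 40, 12 and 4 from 20 to 50 min with acetate and 58 in the mean and 16 at 30 min with CCCP. Exchanging acetate 30 and 50 min gave 15, 70 and 155 (50 against 10 min), and leaving these times out gave a CCCP mean over 10, 20 and 40 min of 276. All printed spots, which also enter genes without a link, gave 15 at 40 min, 7 at 50 min and 72 at 0 min with acetate, 21 at 30 min, 3 at 50 min and 37 at 0 min with CCCP, 15 in the difference and r = 0.344. Differences within time and array number gave 15. The estimated correlation left 3 of 38 list tests.

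Leaving out 1 of the 4 replicates in turn, with the lone arrays assumed to vary like the other groups, gave 11 to 177 genes in the acetate mean. By time it gave 35 to 476, 7 to 129, 5 to 60, 4 to 11 and 3 to 19, with 16 to 338 for 50 against 10 min and 0 to 1 at 0 min. For CCCP it gave 35 to 98 in the mean, 71 to 162, 155 to 275, 2 to 57, 16 to 19 and 0 to 0 by time, 84 to 141 for 50 against 10 min and 0 to 3 at 0 min. The difference ran from 4 to 32, r from 0.328 to 0.458 and list tests from 32 to 39.

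Among the 38 list tests that passed, medians changed sign in 14 cases over the alternatives, all of small size. Sign changes of lists that did not pass were not counted. Acetate and acetoin metabolism in the difference went to 0.030 without background correction, 0.019 with the software's signals, 0.089 with scaling, 0.098 with the slide run as a block, and from -0.13 to 0.063 when leaving out 1 replicate. Median centring, which moved the median of all genes in the difference by -0.24, took SigB to -0.027, SigW to -0.073, iron uptake to -0.013, competence to -0.043 and potassium transport to -0.037. These 5 stayed above the other genes and passed upward (adjusted p from 0.00159 to 0.0254), so the list results did not reverse. Leaving out 1 replicate took potassium transport from -0.044 to 0.20 in the difference, with -0.037 without CCCP replicate 2, and motility with CCCP from -0.38 to 0.046 (without CCCP replicate 1). In the difference iron uptake went to -0.025 without acetate 30 and 50 min. No gene named by size changed sign in an alternative with a test.

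Among 142 results past a threshold, 58 lost their call under scaling, 33 under median centring, 30 with the slide run as a block, 19 with the robust prior, 10 with the software's signals, 4 without background correction, 2 with the replicate block and 0 with it as a random block. Without acetate replicate 1 or 2 the losses were 75 and 77, and without CCCP replicate 1 or 2 they were 41 and 36. Fits of a series alone ended 31 of 110, and genes linked the same way from each series ended 2 of 135. Keeping only spots above background left 3060 genes, with 412 passing at 20 min with CCCP, and ended none of the 142 results past a threshold. As the link already needed such spots, this says nothing about dim ones; 2.65% to 10.4% of control and 3.32% to 8.93% of treated spots had no signal over background. Among the authors' deposited values, 69 moved by more than the spread between arrays, which for lists was the median spread of a gene. The other 344 moved by less, or had the other sign in a result not past its threshold, where the distance was not compared. Genes were linked by nearness to these same values, so the link partly set this agreement.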

Other observations

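The percentile in this part was chosen after the values were seen, as were all groups.

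Of 21 S-box genes of methionine synthesis and uptake 15 fell over 10 to 50 min with acetate (median -1.45). The set was chosen because members had been named for their size. The 15 members outside that naming had a median of -1.31, with a percentile of 0 among 10000 lists matched on signal. This does not decide whether the set is lower beyond the named members. The 15 include yoaD, yusA and yjcJ, which are operon partners of named genes, and the matched lists hold no genes regulated together. With CCCP 5 of the 21 fell (median -0.79), and the difference between the treatments had a median of -0.61 with 0 genes apart.

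The next groups were chosen in the same way, so their values are given without a test. The 10 genes of the yxi operon, which holds yxiF, yxiG, yxiH, yxiJ and yxxG, all fell with CCCP (median -1.35) and 7 fell with acetate (median -0.90). The 8 genes of the histidine operon, with hisZ and hisB, rose at 10 min with acetate (median 2.14); their median was -1.36 at 50 min (0 called) and -0.67 over 10 to 50 min (0 called). With CCCP the 8 fell at 20 min (median -2.80). The 6 measured genes for beta-glucoside and lichenan use, with bglH, licA and licH, rose at 10 min with CCCP (median 2.61) and 0 were called at 50 min (median 0.31).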
